A study of Mus musculus with 5 samples.

How the data were processed

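Cultured label-retaining epidermal cells of newborn Balb/c mice were profiled on 5 Agilent whole-genome mouse arrays after exposure in the womb to sodium arsenite or vehicle, with 2 arrays titled 85 ppm, 2 titled 42.5 ppm and 1 control. Per the labels' protocols, the cells were sorted and selected by adhesion, RNA had an integrity number above 7, and 500 ng was labelled with Cy3. The titles and the exposure entries give opposite doses to the arsenic samples. Groups follow the titles, and the comparison of all arsenic arrays with the control does not depend on this choice.

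The deposited scanner files hold a spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction subtracted a spatially detrended background and corrected a multiplicative trend to give the processed signal, with version 11.5.1.1 for the arsenic arrays and 10.5.1.1 for the control. The scanner and scan settings also differed, with 2 scan passes for the arsenic arrays and 1 for the control. The deposited value table of the series holds log2 values with no stated scale. Set against the scanner files, 99.5% to 99.8% of its probes lay within 0.01 of the log2 processed signal minus the 75th percentile of the array, and its columns have medians of -3.88, -3.82, -4.09, -3.97 and -3.75, so no part of its scale or centring stays unknown.

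In R 4.3.3, log2 of the processed signal minus the 75th percentile of each array was taken for the main setting. Control spots and spots called outliers by the scanner software (83 to 131 on the arsenic arrays and 486 on the control) were left out, and spots of one probe were averaged. Probes were named through accessions and symbols of a RefSeq table of the GRCm38.p6 assembly, used for names alone. By accession 25097 probes matched, 6233 by symbol, 1610 by an older symbol and 156 by another accession, 1682 kept the name in the file and 6396 had none. This gave 21397 genes, 8832 with more than 1 probe, and each gene was read from the probe with the highest mean over the 5 arrays. Probe positions are those of the files, in mm9.

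Genes were tested with limma 3.58.1 (lmFit and eBayes) and Benjamini-Hochberg adjustment, and pass at an adjusted p under 0.05. The doses were compared in a fit of the 4 arsenic arrays, over genes well above background on both arrays of at least 1 dose. The control comparisons used 1 fit of all 5 arrays with 3 group means, over genes well above background on every array of at least 1 group. The lone control was assumed to vary like the arsenic groups, although it was noisier between spots of one probe (SD 0.232 against 0.0568 to 0.0603), so p-values against it may be too small. Nothing states that arrays of one group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

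A probe not well above background, or saturated, on every array of a group has only a bound there. Its difference is given as at least N-fold, the mean of the brighter group over all its replicates (a saturated spot at its value) against the mean in the dimmer group of, per array, the higher of the lowest signal among probes well above background and the signal of the probe itself. Values are means of normalised log2 signals. The adjusted p is that of the fit. On the arsenic arrays 109 to 155 spots were saturated, and 201 on the control. The precision of every value is limited by the number of arrays.

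In all, 35 gene lists were fixed for keratinocyte states, stress and metal responses, growth and signalling pathways, metabolism and markers of other cell types. Each list with at least 5 tested genes was tested with camera in limma, with a preset correlation of 0.01. It was tested again with a correlation estimated from the residuals, under which no list call held in either comparison. With so few arrays this second version has few residual degrees of freedom and little power. The muscle list, with an estimated correlation of 0.041, moved from a camera adjusted p of 3.93e-04 to 0.769 between the doses. Failure under the second version therefore cannot decide against a list. The list medians were also placed among 10000 random lists matched on mean signal, which do not keep the correlation between members of a list. Counts adjusted over a list alone leave the number of lists uncorrected. The groups, tests, gene lists and most alternatives were chosen before the data were examined. So was the rule for named genes: the 10 largest rises and 10 largest falls per comparison among passing genes with a plain symbol, bright on every array of the brighter side and without overlap, filled up by size from genes that differ by at least 1 on the log2 scale but do not pass, together with up to 4 members of each list and 14 keratin, integrin and stem cell genes. Genes of the muscle, cytokine and other lists that passed only adjusted over their list (such as Myl9, Cxcl2, S100a8, Cd52, Laptm5, Col5a1 and Phlda2), and Mtap, Mlana and Xist, were named after their values were seen.

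Alternatives were quantile normalisation, centring on the median or on spike-in probes, normexp background correction (offset 50), the deposited value table, other filters on dim probes, the mean of all probes or each probe on its own, an intensity trend in eBayes, saturated genes left out, a 2-fold minimum, arsenic as 1 group, a replicate block and each arsenic array left out. Normexp used the median spot signal, since the mean spot signal is missing from 4 of the files. Added after the data were seen were leaving out the first 2 array columns, keeping outlier spots, counting only genes whose probes all pass in the same direction, and the mean of probes for the list tests. The list medians without saturated members were also added then. The steps were tested on simulated data with 200 changed genes. The simulated genes were independent, and their true spread was the one already smoothed across genes by eBayes. Real changes may therefore be harder to find than the counts below show. For the doses, 0 of 50 genes changed by 1 on the log2 scale were called, 5 of 50 at 2, 49 of 50 at 4 and 50 of 50 at 6, with 9 false calls among 13784 unchanged genes. For arsenic against control the counts were 0, 0, 36 and 43 of 50, with 6 false calls among 14136. Between the doses, camera gave p under 0.05 for 7% of unchanged lists and 100% of lists shifted by 1. The members of these lists were simulated as independent. In the real data the estimated correlation ran from 0.041 (muscle) to 0.890 (melanocyte) over the 7 lists that passed between the doses. The 7% therefore does not give the rate of false calls for lists of correlated genes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.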

Results

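Gene expression was measured on 5 single-colour Agilent mouse microarrays with 45018 spots each, which carry 41174 different gene probes. The cells came from the epidermis of newborn Balb/c mice whose mothers drank water with sodium arsenite, an inorganic arsenic salt, or with vehicle alone from gestation day 8 to day 18. Pups were 0 to 3 days old. Their label-retaining cells, slowly cycling keratinocytes that keep a BrdU label and are used as a proxy for epidermal stem cells, were grown to confluence before RNA was taken. Of the arsenic arrays, 2 are titled 85 ppm and 2 are titled 42.5 ppm, and 1 array holds the vehicle control. The exposure entry of each arsenic sample gives the opposite dose to its title. Groups are named by title here, so the sign of every difference between the doses turns round if the exposure entry is the right one.

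Between 58.2% and 60.1% of the probes were well above background on the arsenic arrays, and 45.2% on the control array. The control was hybridised to another slide and read with another scanner, scan setting and software version. Slide, scanner and exposure therefore cannot be told apart in any comparison with it. Across 10855 genes well above background on all 5 arrays, Pearson's r across genes was 0.915 to 0.957 between arsenic arrays and 0.819 to 0.831 between an arsenic array and the control. Genes are not independent replicates. A difference of at least 2-fold separated 11.2% to 21.1% of these genes on any pair of arsenic arrays and 46.4% to 47.6% on any arsenic and control pair. All levels below are log2 signal relative to the 75th percentile of the array, and the number of arrays limits their precision.

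The main basal keratins Krt5 and Krt14 were bright on all 5 arrays. Krt5 and Krt17 were saturated on every array, and Krt14, the partner of Krt5 in the basal layer, was saturated on the 4 arsenic arrays with a level of 7.03 on the control. Trp63, the transcription factor that maintains stratified epithelium, lay between 4.91 and 5.26 on the arsenic arrays and at 3.67 on the control. Itga6, the integrin of hemidesmosomes, lay between 5.42 and 6.13 after arsenic and at 4.45 on the control, and Itgb1, another basal integrin, between 2.81 and 3.89 and at 3.82. Cd34, a bulge stem cell marker, was low and dimmer on each arsenic array, down to -5.68, than on the control, at -2.74. Krt15, a marker of slowly cycling bulge and basal cells, lay at 2.75 and -1.80 on the arrays titled 85 ppm, -3.44 and -2.84 on those titled 42.5 ppm, and 1.85 on the control, so the arrays titled 85 ppm lay on both sides of it. The suprabasal pair Krt1 and Krt10 stood out on the first 85 ppm array, with Krt1 at 3.09 and Krt10 at 5.21 there, against -2.38 or less for Krt1 and 0.80 or less for Krt10 on each other array. The simple epithelial keratins Krt8 and Krt18 were bright on all arrays, with some spots saturated, between 4.38 and 7.78 for Krt8 and between 5.47 and 7.85 for Krt18. Melanocyte genes were bright on the control too, with Dct saturated at 7.95 and Mlana at 6.53. On the arsenic arrays Dct lay between -3.63 and 6.46 and Mlana between -1.66 and 4.46. Pmel, at 3.47 on the control, lay within the range of the arsenic arrays.

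**Figure D1:**
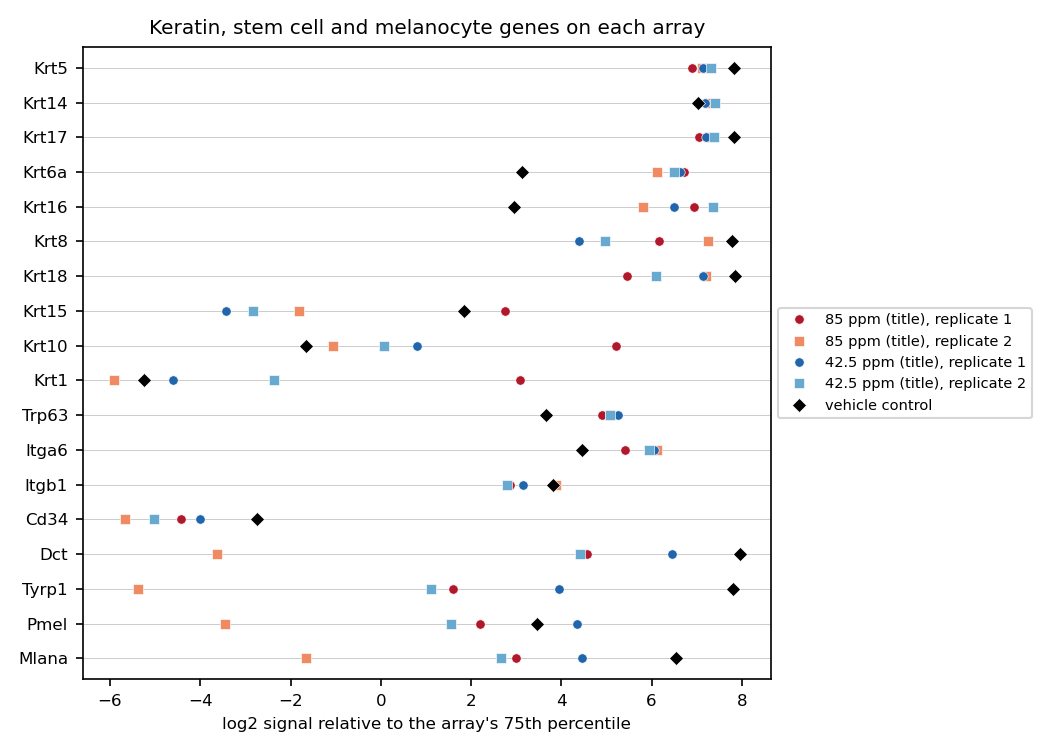
Levels of keratin, integrin, stem cell and melanocyte genes on each of the 5 arrays, as log2 signal relative to the 75th percentile of the array. Each point is 1 array, coloured by group, and Krt1, Krt10 and Krt15 spread widely among the arsenic arrays while Krt5 and Krt14 stay at the top of the scale.

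The arsenic arrays against the control address whether exposure in the womb alters gene expression in epidermal stem cells. Lce3c, a late cornified envelope protein, had the largest rise. It had a mean level of 4.48 ± 0.88 (SD, n = 4) on the arsenic arrays and was not well above background on the control, so it was at least 223-fold higher (limma, adjusted p = 0.00845). Klk7, the protease that sheds cornified cells, was at least 214-fold higher (adjusted p = 0.00845), and Calm4, a calmodulin-like protein of differentiating keratinocytes, at least 164-fold (adjusted p = 0.0249). Of the 32 tested members of the list of suprabasal differentiation and cornified envelope genes, 10 rose and 1 fell, 29 had a positive difference, and adjusted over the list alone 11 rose and 1 fell. The shift of the whole list passed the camera test with a preset correlation (adjusted p = 7.24e-05), with a median log2 difference of 1.98. With the 13 members that have only a bound set at that bound, the median was 1.55. The list did not pass after centring the arrays on the spike-in probes (adjusted p = 0.0629). With an estimated correlation, which has little power here, the adjusted p was 0.937.

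Of the 10 largest rises, Calm4, Cnfn and Krtdap belong to that list. Endou, a poly(U)-specific endoribonuclease, was at least 89.9-fold higher and Cnfn, the cornified envelope protein cornifelin, at least 70.3-fold higher (adjusted p = 0.0159 and 0.0106). Kprp, a proline-rich keratinocyte protein, was at least 67.6-fold higher, Krt78, a suprabasal keratin, at least 38.3-fold, and Krtdap, a differentiation-associated protein, at least 35.6-fold (adjusted p = 0.00845, 0.0214 and 0.0479). Lce1a1, a further envelope gene, was at least 24.1-fold higher (adjusted p = 0.0247). Plbd1, a phospholipase-like protein, was at least 40.4-fold higher and the ligand gene Wnt3 at least 33.9-fold (adjusted p = 0.00845 and 0.0465). A second probe gave log2 differences of 8.72 for Lce3c, 7.68 for Calm4 and 4.74 for Wnt3, and the further probes of Klk7 gave 7.39 to 8.67. By mm9 probe positions, Lce3c lies on chromosome 3 (92749506 to 92749565), Klk7 on chromosome 7 (51071252 to 51071311), Calm4 on chromosome 13 (3837682 to 3837741), Endou on chromosome 15 (97541632 to 97541691), Cnfn on chromosome 7 (26152727 to 26152786) and Krt78 on chromosome 15 (101776589 to 101776648). The median level of the suprabasal list was 1.62 and -0.33 on the arrays titled 85 ppm, 0.69 and 2.37 on those titled 42.5 ppm, and -2.16 on the control. Melanocyte genes, whose median level was 1.80 on the control and -4.39 to 0.88 on the arsenic arrays, moved with the groups in the opposite direction.

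**Figure D2:**
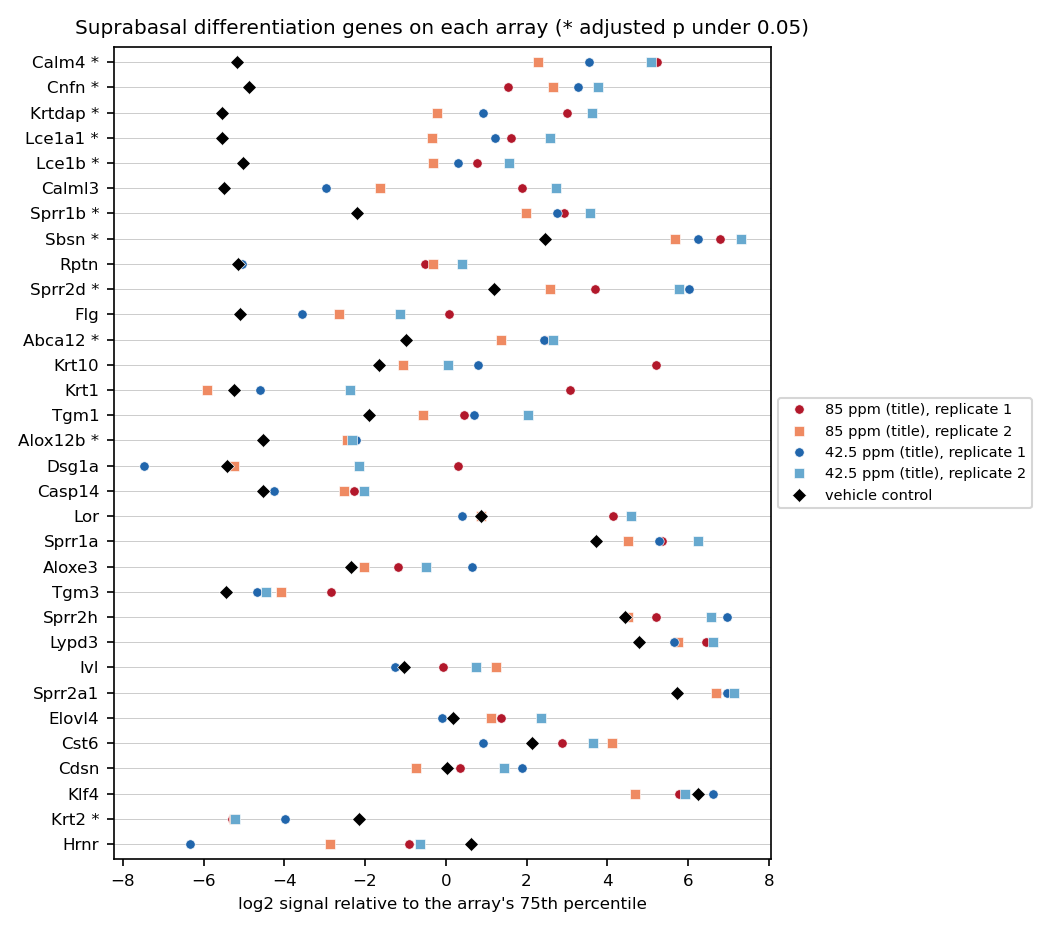
Levels of suprabasal and cornified envelope genes on each array, as log2 signal relative to the 75th percentile, with the 4 arsenic arrays and the control marked by group. Calm4, Cnfn, Krtdap and Lce1a1 are not well above background on the control and lie above it on every arsenic array.

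Some basal and stress keratin genes passed as well, although neither list did as a whole. Krt6a, a keratin of activated and wounded epidermis, had a mean of 6.49 ± 0.26 (SD, n = 4) against 3.14 on the control, a log2 rise of 3.36 (SE 0.35, adjusted p = 0.0180; chromosome 15, 101520862 to 101520921). Its close relative Krt6b rose by 3.79, and their partner Krt16, saturated on 2 of the 4 arsenic arrays, by 3.71 or more (adjusted p = 0.0207 and 0.0301). Of the 12 tested stress and simple epithelial keratins, 6 rose and 1 fell, or 6 and 3 adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.508). Krt19, a simple epithelial keratin, differed by -4.44 with 2 of the 4 arsenic arrays well above background, and did not pass (adjusted p = 0.0830). Krt8 did not pass either (adjusted p = 0.0641) and was saturated on the control and on 1 arsenic array, so its difference has no clear size. Among 26 basal and stem cell genes 7 rose and 1 fell, or 8 and 3 adjusted over the list alone (list adjusted p = 0.280). Lamb3, a chain of the basement membrane laminin, rose by 4.03 (SE 0.60, adjusted p = 0.0260), Bcl11b, a transcription factor of epidermal development, by 3.06, Sfn, the epithelial adaptor stratifin, by 2.98 and Trp63 by 1.41, with 4.40 from its second tested probe (adjusted p = 0.0269, 0.0172 and 0.0398). Itga6 differed by 1.43 (-1.30 to 1.36 from its other probes), Krt15 by -3.18 and Cd34, well above background on 3 of the 4 arsenic arrays, by -2.04, none of which passed. Itgb1 differed by -0.64 from a probe at the edge of the array, while a second probe gave 3.38 and the third was not well above background on every array of either group. Epithelial junction and mesenchymal genes split, with 6 of 30 higher and 5 lower (6 and 7 adjusted over the list alone, list adjusted p = 0.765). Jup, the desmosome protein plakoglobin, rose by 3.93 (adjusted p = 0.0113) and Dsg3, a desmosomal cadherin, by 3.74 (adjusted p = 0.0265), although the second Dsg3 probe gave 0.59.

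Metal and stress responses were mixed. Mt1, the metal-binding metallothionein, had a mean of 6.26 ± 0.19 (SD, n = 4) against 4.10 on the control and rose by 2.17 on the log2 scale (SE 0.29, adjusted p = 0.0238; chromosome 8, 96704011 to 96704070), with 0.77 from its second probe. Slc39a8, a zinc and cadmium importer, was at least 9.46-fold higher, and the zinc exporter Slc30a1 rose by 2.04 (adjusted p = 0.0207 and 0.0368), while their second probes gave 0.51 and -0.17. With Mt4, the metallothionein of stratified epithelium, at least 1.21-fold higher (adjusted p = 0.0319, but -0.15 on the log2 scale and not passing with normexp background correction), 4 of 9 metal handling genes rose and 0 fell by limma, with 4 rising and 0 falling at an unadjusted p under 0.05 and adjusted over the list alone, and the list did not pass (adjusted p = 0.221). Among 31 targets of NRF2, the regulator of the oxidative stress response, 1 rose and 1 fell, and 0 passed by limma adjusted over the list alone, against 8 higher and 5 lower at an unadjusted p under 0.05 (list adjusted p = 0.628). Nqo1, a quinone reductase, was at least 53.8-fold higher and Gclm, a subunit of the enzyme that starts glutathione synthesis, at least 5.74-fold, and neither passed (adjusted p = 0.0548 and 0.118). The heme catabolism enzyme Blvrb differed by 4.54 and the glutathione transferase Gsta2 by 3.50 without passing. Heat shock genes gave 2 higher and 3 lower of 19, the same counts adjusted over the list alone, with Dnaja1 and Bag3, a pair of co-chaperones, up by 2.80 and 1.87 and Chordc1, another, down by a log2 difference of -2.19, with 0.08 from its second probe. Hspa1b, the inducible Hsp70, differed by 4.11 without passing (adjusted p = 0.0999). Of 26 genes of endoplasmic reticulum stress 5 fell, or 6 adjusted over the list alone with 1 higher. Among them Hspa5, the main chaperone of that compartment, was at least 4.22-fold lower and Chac1, a glutathione-degrading enzyme induced by ATF4, differed by -2.84 (adjusted p = 0.0420 and 0.0310). The arsenic handling list of 13 genes held 1 call, Mat2a, which makes the methyl donor S-adenosylmethionine and was at least 5.23-fold lower (adjusted p = 0.0240), also the sole call adjusted over the list alone, and the phosphate transporter Slc20a1 differed by -1.26 without passing, with 1.52 from its other probe.

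Several of the genes with the largest falls came from probes in the first column of the array, where a larger share of probes was far brighter on the control. Of 727 probes in the first 2 columns, 11.3% were at least 16-fold brighter on the control than on the arsenic arrays, against 1.47% of the 39823 other probes. These columns were chosen after the falls were seen. Adgrg4 (at least 7942-fold lower), Parvb (-12.50), Gng3 (-10.84), Ccdc40 (-10.53), F9 (at least 1268-fold), Rnase1 (-10.01) and Pax4 (at least 526-fold) all lie in column 1. Parvb and Gng3 were well above background on 1 of the 4 arsenic arrays, so the sizes of their differences are uncertain. A second Rnase1 probe elsewhere gave 0.98. Away from the edge, Pitx1, a homeobox factor of hindlimb identity, differed by -11.66 (SE 1.84, adjusted p = 0.0282; chromosome 13, 55926417 to 55926476), with 2 of the 4 arsenic arrays well above background. Ltf, which encodes the iron-binding defence protein lactoferrin, was at least 962-fold lower (adjusted p = 0.00888; chromosome 9, 110942873 to 110942932), with -9.03 from its second probe, and Foxg1, a forkhead factor of the forebrain and ectoderm, at least 650-fold lower (adjusted p = 0.0155; chromosome 12, 50487747 to 50487806).

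Cytokine and defence genes changed in both directions, 6 of 29 higher and 4 lower (6 and 5 adjusted over the list alone, list adjusted p = 0.628). Lcn2, the siderophore-binding lipocalin, fell by 6.15 on the log2 scale, the neutrophil attractant Cxcl5 by 6.42 and the granulocyte growth factor Csf3, well above background on 3 of the 4 arsenic arrays, by 5.91 (adjusted p = 0.0397, 0.0458 and 0.0315). Il33, an epithelial alarmin, was at least 39.8-fold higher (adjusted p = 0.0417). Tgfbi, a matrix protein induced by TGF-beta, rose by 5.40 (SE 0.35, adjusted p = 0.00888), and the contractile genes Actc1 (at least 47.5-fold) and Tagln (4.66, with 4.96 from its second probe) rose as well (adjusted p = 0.0108 and 0.0111). In the muscle list 3 of 17 were higher and 2 lower (4 and 2 adjusted over the list alone, list adjusted p = 0.280), and Myl1, a skeletal light chain, was at least 4.88-fold lower. Of 24 Hedgehog and TGF-beta genes 2 rose and 3 fell, the same adjusted over the list alone. Cdkn2a, which encodes the p16 and p19 growth inhibitors, fell by 5.19 (SE 1.04, adjusted p = 0.0397) with 3 of the 4 arsenic arrays well above background, but it was low only on the arrays titled 42.5 ppm and its probe lies in column 2.

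All 11 melanocyte genes had a negative difference with a median of -4.68, and the list missed the threshold (adjusted p = 0.0563). It passed after quantile normalisation (camera, adjusted p = 0.0243) and spike-in centring (1.69e-06), but not with the mean of probes (0.0912) or an estimated correlation (0.937). Relative to all genes the list stood at -4.55. It stood at -5.43 without the first array titled 85 ppm and at -3.66 without the second. Without the first titled 42.5 ppm it stood at -5.08, and without the second at -3.82. Of its genes, 2 of 11 were lower and 0 higher by limma (4 lower at an unadjusted p under 0.05), and the same adjusted over the list alone. Tyrp1 and Dct, enzymes of melanin synthesis, were at least 180-fold and at least 31.9-fold lower without passing (adjusted p = 0.136 and 0.311), with the Tyrp1 probe in column 1. The pigment transporters Slc45a2 and Oca2 differed by -5.28 and -5.22, also without passing. Oca2 was well above background on 3 of the 4 arsenic arrays. Plp1, the myelin protein of Schwann cells, fell by 6.86 (SE 1.39, adjusted p = 0.0408), with -4.51 from its second probe, in a Schwann and neural list with 1 of 13 higher and 2 lower (1 and 4 adjusted over the list alone, list adjusted p = 0.628).

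Ribosomal protein genes had a median difference of -0.56 and 44 of 54 were negative, which missed the threshold (adjusted p = 0.0563). After quantile normalisation the list stood at 0.06 relative to all genes, the opposite direction (adjusted p = 0.613). Of its members 40 were saturated on at least 1 array, so the list median is set largely by the ceilings of the scans, and the 14 others had a median of 0.21 with 8 positive. Rps6, Rpl10a and Rpl30 rose by 2.35, 1.91 and 1.62 (adjusted p = 0.0207, 0.0247 and 0.0307) among 3 higher and 3 lower, and adjusted over the list alone 1 rose and 0 fell, against 4 and 17 at an unadjusted p under 0.05 by limma. Rpl10, at least 2.54-fold lower (adjusted p = 0.0394), was read by a probe placed on chromosome 8, while its other probe gave 1.60.

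None of the remaining lists passed as a whole (adjusted p from 0.484 to 0.981). Among immediate early and MAPK genes 3 of 27 rose and 5 fell (4 and 6 adjusted over the list alone). Jun, the AP-1 subunit, rose by 3.20 and the growth factor gene Nrg1 by 3.38 (-1.79 to 3.79 from its other probes). Egr3, an early response factor, was at least 4.45-fold higher. Glycolysis and hypoxia genes gave 2 higher and 4 lower of 33 in both counts, with the pyruvate kinase gene Pkm up by 4.19 (1.02 to 3.51 from its other probes), the lactate exporter Slc16a3 up by 4.41 and the hexokinase gene Hk2 at -3.04. In the respiratory chain 3 of 32 rose and 2 fell (2 and 1 adjusted over the list alone), with Cox6c up by 1.95, Sdhd up by 1.92 and Atp5a1 at -1.55 from one probe and 1.25 from the other. Of 28 p53 targets and senescence genes 1 rose and 4 fell, in both counts, with the inhibitor gene Cdkn1b at -2.73 from one probe and -0.26 from the other. The TGF-beta receptor gene Tgfbr1 and its target Id1 fell by 3.01 and 2.83 in the Hedgehog and TGF-beta list. Notch genes gave 1 higher and 2 lower of 12 in both counts, with Notch2 up by 1.86 (0.29 and 0.63 from its other probes) and Rbpj, the nuclear effector of the pathway, at -3.18. Of 22 Wnt genes 1 rose and 3 fell, among them Nkd1 at -3.46 and Wnt7b at -2.74. DNA repair gave 2 higher and 2 lower of 35, with Parp1, a sensor of strand breaks, at -1.72 and the helicase gene Ercc2 at least 1.87-fold higher. Adjusted over the list alone, 0 Wnt and 0 repair genes passed by limma, against 2 higher and 5 lower and 5 higher and 8 lower at an unadjusted p under 0.05. Among 30 DNA and histone methylation enzymes 1 rose and 3 fell in both counts, including the methyl-DNA reader Mecp2 at -2.27 and the Polycomb gene Cbx4 at -2.17.

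Of 13 hair follicle and sebaceous genes 2 rose and 1 fell in both counts, with Tchh, the root sheath protein trichohyalin, up by 3.13 and the lipid desaturase gene Scd1 at least 18.3-fold higher. Of 20 fibroblast genes 4 fell in both counts and 0 rose by limma, against 2 higher and 5 lower at an unadjusted p under 0.05, with the matrix genes Fbln2 at -3.87 and Ogn at least 5.41-fold lower and Twist2, a dermal transcription factor, at -4.83 with 2 of the 4 arsenic arrays well above background. Leukocyte markers gave 1 higher and 1 lower of 17 in both counts, the lysosomal protein gene Cd68 at 3.05 and Cd8a at least 8.39-fold lower. Imprinted genes gave 1 higher and 3 lower of 18 (2 and 3 adjusted over the list alone), the amino acid transporter Slc38a4 being at least 5.45-fold higher. In the pluripotency list Klf2 alone of 6 genes passed, also adjusted over the list alone, at 1.47 from one probe and -0.29 from the other. In both counts 0 genes passed by limma among 42 cell cycle genes, 27 interferon genes, 13 endothelial markers and 6 sex-linked genes. At an unadjusted p under 0.05 the cell cycle list had 1 higher and 2 lower, the interferon list 1 and 5, and the endothelial and sex-linked lists 0. Ifit3, an interferon-induced antiviral gene, differed by -6.01 without passing (adjusted p = 0.0873). Adipocyte (4 genes), red blood cell (4) and Merkel cell markers (2) were too few for a list test, with 0 calls by limma and 0 genes at an unadjusted p under 0.05. Median, mean and test differed in sign for the fibroblast, heat shock, Notch and pluripotency lists.

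By limma with Benjamini-Hochberg adjustment, 3216 of 14336 genes passed, 1434 higher after arsenic and 1782 lower (44.6% higher). These p-values take the spread of the lone control from the arsenic arrays, although the control was noisier between spots of one probe (SD 0.232 against 0.0568 to 0.0603), so the count may be too high. The groups did not overlap for 72.1% of genes, where chance gives 40.0%. The split depends on the scaling: the share of higher calls was 60.2% after quantile normalisation, 58.9% after median centring, 92.7% after spike-in centring and 34.0% with normexp background correction, as the median of all genes, -0.14 in the main scaling, moved by 0.20, 0.23, 1.37 and -0.15. Probes of one gene often differed in this comparison: across 2835 genes with 2 probes, r between the probes was 0.257 (95% interval 0.223 to 0.291), against 0.816 (0.803 to 0.828) for the difference between the doses. Between the 2 arrays titled 85 ppm r was 0.779 (0.764 to 0.793), and between those titled 42.5 ppm 0.587 (0.562 to 0.611), so probes of one gene also differ within a slide. Of 1278 called genes with several tested probes, 183 had all probes passing in the same direction, 91 higher and 92 lower, and in the suprabasal list 3 were among them. In limma 0 genes passed without the first array titled 85 ppm (4881 at an unadjusted p under 0.05, smallest adjusted p = 0.0688) and 0 without the second (4852, 0.0686). Without the first array titled 42.5 ppm 1422 passed and without the second 828. With 1 array fewer the spread is less well estimated, so these losses do not show that the differences rest on single arrays.

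**Figure D3:**
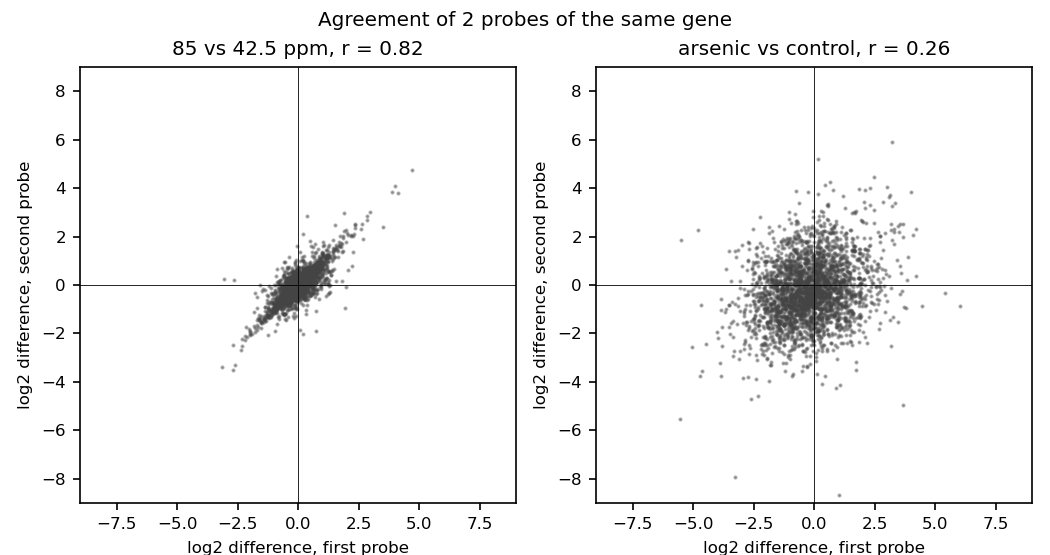
Log2 difference given by one probe of a gene against that given by its other probe, for 2835 genes with 2 probes well above background on all arrays, between the doses and between arsenic and control. Each point is 1 gene, and the points lie along the diagonal for the doses (r = 0.816) and scatter for arsenic against control (r = 0.257).

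Each dose alone was also set against the control, the same array in both cases, to see how far the differences were shared. Krt6a rose by 3.28 on the arrays titled 85 ppm and by 3.43 on those titled 42.5 ppm (adjusted p = 0.0270 and 0.0233), and Mt1 by 2.28 and 2.05 (adjusted p = 0.0318 and 0.0326). Tgfbi rose by 6.81 and 3.99 (adjusted p = 0.0123 and 0.0206). Cdkn2a differed by -1.03 on the arrays titled 85 ppm, which did not pass, and by -9.34 on those titled 42.5 ppm (1 of 2 well above background), which did (adjusted p = 0.542 and 0.0251), while its difference between the doses did not pass. In all, 2262 of 14336 genes passed for 85 ppm, 1035 higher and 1227 lower, and 2639 for 42.5 ppm, 1213 higher and 1426 lower. Higher calls shared by both numbered 883, where independent lists would share 87.6, and shared lower calls 958, where they would share 122.05. The log2 differences correlated across genes at r = 0.885, against 0.667 in 100 simulations of unchanged groups against a shared control, and the covariance was 2.77 against 0.262, a difference of 2.51. The single control array was subtracted in both comparisons and cannot be split. The simulations gave it the spread of the arsenic arrays, although it was noisier between spots and lay on another slide. Part or all of the excess may therefore come from the control array. No gene passed for 42.5 ppm when any 1 arsenic array was left out (0 by limma, 4845 to 5059 at an unadjusted p under 0.05), nor for 85 ppm without either of its own arrays (0 by limma, 4011 and 3898), again with fewer arrays to estimate the spread.

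The 2 doses, both on 1 slide, address whether the amount of arsenic matters. No single gene passed between them. Cdkn2a, which encodes p16 and p19, lay at 1.43 and 2.74 on those arrays and at -7.35 and -5.11 on the arrays titled 42.5 ppm, a fitted log2 difference of 8.31 (SE 0.93, n = 2 per dose, adjusted p = 0.282; chromosome 4, 88920545 to 88920604). Cnn1, the smooth muscle protein calponin, differed by 6.57 (SE 1.28, adjusted p = 0.364; chromosome 9, 21913058 to 21913117). Both were well above background on 1 of the 2 arrays titled 42.5 ppm, so the sizes of these differences are uncertain. The muscle list shifted upward with the lowest adjusted p of all lists, with 13 of 16 members positive and a median of 0.69 (camera, adjusted p = 3.93e-04; adjusted p = 0.769 with an estimated correlation).

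Other contractile genes had differences of 5.31 for the skeletal actin Acta1 and 4.12 for the smooth muscle actin Acta2 (saturated on 1 array titled 85 ppm, with 0.76 to 4.72 from its other probes). Further values were 3.50 for the cardiac actin Actc1, 3.37 for the light chain Myl9 and 2.26 for Tagln. None of the muscle list passed over all genes by limma, with 6 higher at an unadjusted p under 0.05, and adjusted over the list alone 6 were higher (Acta1, Acta2, Actc1, Cnn1, Myl9 and Tagln). The neighbouring inhibitor gene Cdkn2b, which encodes p15, differed by 3.37 and the growth arrest gene Gadd45g by 2.36, in a list of 28 p53 targets and senescence genes that shifted upward with a median of 0.28 and 19 positive (adjusted p = 0.0493; adjusted p = 0.769 with an estimated correlation), and 1 of its genes, Cdkn2a, passed adjusted over the list alone. The p53 list stood at 0.34 relative to all genes, and without the first array titled 85 ppm at 0.09 and did not pass (adjusted p = 0.403). It did not pass either without the first or the second array titled 42.5 ppm (0.0710 and 0.0679) or with the mean of probes (0.0943). Nuak1, a stress-responsive kinase, differed by 4.70 (SE 0.64; chromosome 10, 83833698 to 83833757) with 4.63 to 4.74 from its other probes. Stmn2, a neuronal microtubule regulator, was at least 46.2-fold higher, the serine protease gene Prss46 at least 18.6-fold and Ankrd1, a stretch-induced cofactor, at least 12.3-fold, none of them past the threshold (adjusted p = 0.282, 0.282 and 0.348). The antigen-presenting gene H2-Ab1 differed by 5.02 and the receptor gene Klra15 by 4.97, with 1 of the 2 arrays titled 42.5 ppm well above background. The transcription factor gene Sox11 differed by 4.88, with 0.71 to 4.76 from its other probes. Klra15 fell to 2.71 without the second array titled 42.5 ppm and Gadd45g to 1.16 without the first titled 85 ppm.

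The cytokine list was lower for the arrays titled 85 ppm, with a median of -0.85 and 22 of 29 negative (adjusted p = 0.00388; adjusted p = 0.769 with an estimated correlation). This rests largely on the second of these arrays, where the median level was -1.21 against 0.96 to 1.01 on the other arsenic arrays. Without it the list stood at -0.21 relative to all genes and did not pass (adjusted p = 0.256). Cxcl3, a neutrophil attractant, differed by -4.87 (SE 0.29; chromosome 5, 91216694 to 91216753), and adjusted over the list alone Cxcl2, Cxcl3 and S100a8 were lower. Cxcl10, an interferon-induced chemokine, differed by -3.28 and Il33 by -3.11, while Il18 gave 2.86. Leukocyte markers tested lower with a median of -1.29, or -1.06 with 3 bounded members at their bound, and 13 of 16 negative (adjusted p = 0.0230; adjusted p = 0.769 with an estimated correlation), among them Tyrobp at -3.11, the macrophage marker Adgre1 at -3.07 and the lysozyme gene Lyz2 at -2.99 (-0.73 from its other probe). Adjusted over the list alone H2-Ab1 was higher and Cd52 and Laptm5 lower. The list did not pass without the second array titled 85 ppm or without the first titled 42.5 ppm (adjusted p = 0.0611 and 0.196). Among the 10 largest falls, Cd83, a marker of mature dendritic cells, was at least 14.7-fold lower and the Fc receptor gene Fcgr1 at least 5.81-fold lower, with the lectin gene Clec4d at -4.69 and the integrin gene Itgb7 at -4.82. Limch1 differed by -5.09, the antimicrobial S100a7a by -4.59 and the endothelial receptor Kdr by -4.59, and Ccnjl and F10 were at least 16.5-fold and at least 5.37-fold lower. Tyrobp, Adgre1, Clec4d, Limch1 and S100a7a were well above background on 1 of the 2 arrays titled 85 ppm. Without the second array titled 85 ppm the differences were -1.5 for Cxcl10, -1.54 for Il33, -1.23 for Adgre1, 0.13 for Lyz2, -2.85 for Clec4d and -2.24 for Limch1. Without the first titled 42.5 ppm they were 0.85 for Il18, -1.59 for Itgb7 and -2.37 for S100a7a.

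The melanocyte list had all 10 members negative with a median of -2.74 (adjusted p = 0.0161; adjusted p = 0.769 with an estimated correlation) and 0 genes past in limma at any adjustment or at an unadjusted p under 0.05. Relative to all genes it stood at -2.68, at -0.78 without the second array titled 85 ppm and at -1.59 without the first titled 42.5 ppm, and it did not pass without either (adjusted p = 0.256 and 0.486). Its members differed most between the arrays titled 85 ppm: Dct was at 4.58 and -3.63 there and at 6.46 and 4.42 on the arrays titled 42.5 ppm, Tyrp1 at 1.61 and -5.38, and Pmel at 2.20 and -3.44 against 4.35 and 1.54. Kit, the receptor that melanoblasts need, differed by -3.49 with 1 of the 2 arrays titled 85 ppm well above background, or by -1.75 without the second of them. Cell cycle genes shifted downward with a median of -0.51 and 31 of 42 negative (adjusted p = 0.0161; adjusted p = 0.856 with an estimated correlation), including the replication licensing genes Cdc6 at -3.31, Cdt1 at -2.47 and Mcm5 at -2.41 and the cyclin gene Ccne2 at -2.45 (1 of the 2 arrays titled 85 ppm well above background). The list had 0 genes past in limma at either adjustment and 9 lower at an unadjusted p under 0.05. The direction of that list rests on the second array titled 42.5 ppm, whose median was 3.80 against -0.33 on the first, and 1.75 and 0.94 on the arrays titled 85 ppm, and it turned to 1.46 relative to all genes without that array. All 54 ribosomal protein genes had negative differences, with a median of -0.19 (adjusted p = 0.00388; adjusted p = 0.769 with an estimated correlation), such as Rpsa and Rpl18 at -0.75 each, but the list stood at 0.01 relative to all genes, the opposite direction, after quantile normalisation (adjusted p = 0.410). Of these genes 38 were saturated on at least 1 arsenic array and give no clear size or direction. Mt2, saturated on every arsenic array, differed by -0.16, which reflects the scan ceilings after scaling. The list median and the shared sign of the 38 genes are thus set largely by these ceilings. The 16 others, all negative, had a median of -0.44.

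The lists of stem cell, stress and metal genes did not pass, although the NRF2 list had a median of 0.35 and 21 of 31 positive (camera, adjusted p = 0.214). Of 32 tested lists, 14 lay outside the central 95% of the random lists, and the NRF2 list lay above 100% of them. Its median level was 4.08 on the second array titled 85 ppm, 2.38 on the first and 2.75 and 2.70 on those titled 42.5 ppm, so this comes from 1 array. Krt15 differed by 3.61 (SE 1.60) and Krt1, well above background on 1 of the 2 arrays titled 85 ppm, by 2.07 (0.30 from its other probe). Krt10 differed by 1.65 and Krt8, saturated on 1 array titled 85 ppm, by 2.02 or more. Lgr5, a follicle stem cell receptor, was at least 1.60-fold higher. Krt6a, Itga6, Itgb1 and Trp63 differed by -0.22 to 0.40, with -1.01 from the second Trp63 probe, and Cd34, well above background on 1 of the 2 arrays titled 85 ppm, by -0.54. Krt5, Krt14 and Krt17 were saturated on every arsenic array and Krt16 and Krt18 on some, so they give no measure of a difference. Among antioxidant genes Gsta3 differed by 2.98, Gsta4 by 1.80, Cat, the peroxide-degrading catalase, by 1.38 and the thioredoxin reductase Txnrd1 by -1.54. Mt1 differed by 0.23 (1.22 from its other probe) and the zinc importer Slc39a4 by 3.68, while Mt2 was saturated on every arsenic array. Arsenic methyltransferase As3mt, well above background on 1 of the 2 arrays titled 85 ppm, differed by -1.15, the glycerol channel Aqp3 by 1.80, and Aqp9, which also carries arsenite, was at least 2.15-fold lower. The heat shock genes Hspa1a, Hspa1b and Cryab differed by -1.36, -1.31 and -1.38, with -0.22 from the other Cryab probe. Matrix and growth factor genes were spread, with Postn at 3.41, Col5a2 at 3.01, Tgfbi at 2.83, Tgfb2 at 2.90, Serpine1 at 2.40, Wnt7a at -4.10, Nrg1 at -3.43 (-3.61 to -0.73 from its other probes), Igf2 at -2.77 and the envelope genes Sprr2d and Sprr2h at -2.77 and -1.91. Many of these values rest on 1 array. Without the second array titled 85 ppm Slc39a4 differed by 0.65, Gsta3 by 1.17, Gsta4 by 0.23, Cat by 0.47, Cryab by -0.55 and Serpine1 by -0.75. Without the first titled 85 ppm Krt15 differed by 1.34, Krt1 by -2.43, Krt10 by -1.49, Aqp3 by 0.40 and As3mt by 0.21. Without the first titled 42.5 ppm Hspa1a differed by -0.19 and Hspa1b by 0.10. Adjustment over a list alone leaves the number of lists uncorrected, and none of the genes that passed by it passed over all genes. By it Snai1 was higher among junction and mesenchymal genes and Kdr lower among endothelial genes. Among fibroblast genes Col5a1, Col5a2 and Postn were higher and Twist2 lower. Krt75 was lower among hair follicle genes, and Tgfbi higher among Hedgehog and TGF-beta genes. Phlda2 and Sgce were lower among imprinted genes, as was Nrg1 among MAPK genes. Ncam1 and Stmn2 were higher among Schwann and neural genes, and Krt23 lower among stress keratin genes. The 25 lists other than the 7 named above did not pass, with adjusted p from 0.103 for DNA repair to 0.960 for sex-linked genes, and the adipocyte, red blood cell and Merkel cell lists were again too small to test. Median, mean and test differed in sign for the Schwann and neural, interferon, metallothionein, methylation enzyme and Wnt lists.

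**Figure D4:**
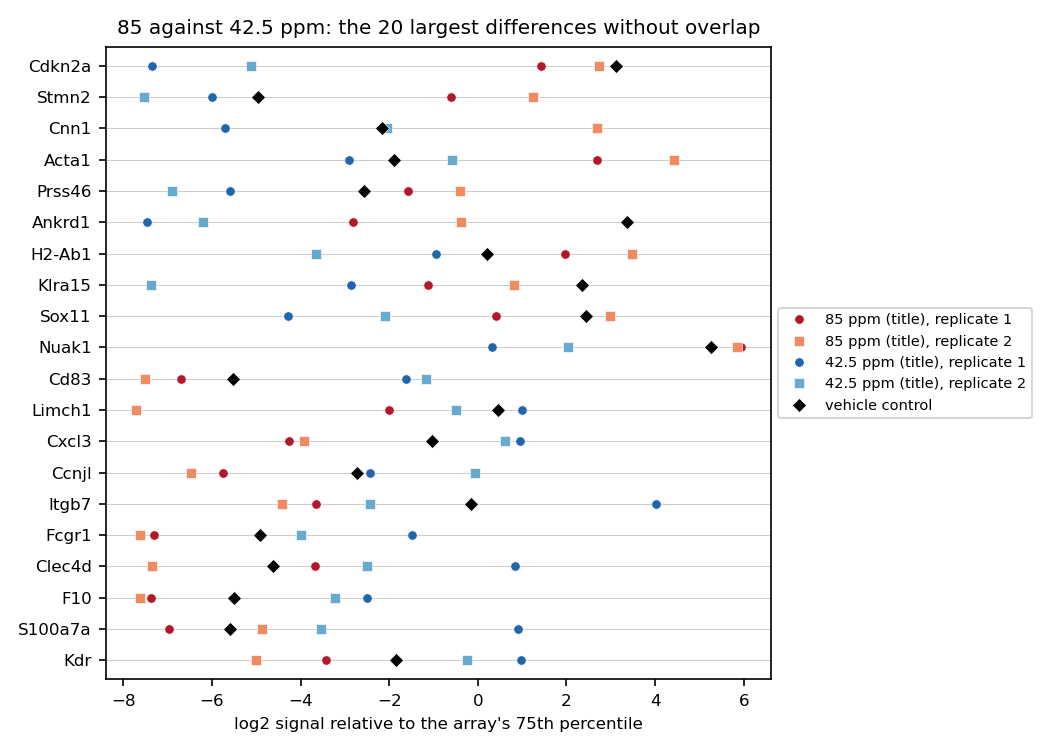
Levels on each of the 5 arrays, the control among them, of genes with the largest differences between the doses, as log2 signal relative to the 75th percentile. Each point is 1 array; Cdkn2a, Cnn1 and Nuak1 lie above every 42.5 ppm array on both arrays titled 85 ppm, and Cxcl3 and Cd83 below.

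In the limma test over 13984 genes 0 passed (smallest adjusted p = 0.282), and 1498 had an unadjusted p under 0.05, 740 higher and 758 lower, where about 699 would by chance. The arrays of the doses did not overlap for 45.4% of genes, where chance gives 33.3%, and 873 of these were at least 2-fold higher and 776 at least 2-fold lower. With 2 arrays per dose the median SE was 0.323 on the log2 scale. In simulated data 5 of 50 genes changed by 2 on that scale were found, and 49 of 50 changed by 4. Those data had independent genes with a spread smoothed across genes, so real changes may be harder to find. On the real arrays Cdkn2a differed by 8.31 and did not pass (limma, adjusted p = 0.282).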

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

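The alternative scalings used in this part were planned. Their use to weigh a cause, and all other tests in this part, were chosen only after the results they bear on were seen.

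Many genes passed between the arsenic arrays and the control, and the slide changes with the exposure. Scaling is argued against as the whole cause, since 2830 of the 3216 genes still passed in the same direction after quantile normalisation, 2290 after median centring and 1859 after spike-in centring. Differences in the signal of single probes between the slides are consistent with the weak correlation of the differences given by 2 probes of a gene, 0.257 against 0.816 between the doses, 0.779 between the arrays titled 85 ppm and 0.587 between those titled 42.5 ppm, all within the arsenic slide, and all probes passed in the same direction for 14.3% of called genes with several tested probes. Arsenic exposure cannot be told apart from the slide, because no slide holds both groups.

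Probes at the left edge of the control array form a pattern of their own, with 33.3% of the 237 probes in rows 150 to 350 of the first 2 columns at least 16-fold brighter there. For the 25 bright edge probes whose gene has another probe, the median control minus arsenic difference was 6.12 at the edge and -0.025 (quartiles -1.48 to 0.72) for the other probes. For 176 probes elsewhere that were also at least 16-fold brighter on the control the values were 4.68 and 1.30. A local fault of the control array is therefore a candidate explanation, and the large falls of Adgrg4, Parvb, Gng3, Ccdc40, F9, Rnase1 and Pax4 rest on such probes. No biological explanation was tested.

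Melanocyte genes stood apart on the second array titled 85 ppm. The list differed by a median of -3.26 between the 2 arrays titled 85 ppm and by -2.25 between those titled 42.5 ppm. Between the doses it differed by -2.74, and 9 of 10 members differed more within 85 ppm than between the doses. The titled dose cannot account for the spread within a dose. Means of 2 arrays vary less than single arrays, so these values cannot decide whether dose adds to the difference between the doses. The median difference of 0.014 over all 13984 genes cannot address a dimmer array, since every array was scaled to its 75th percentile. Before scaling, the 75th percentile of the processed signal was 455 on the second array titled 85 ppm. It was 531 on the first, and 459 and 405 on the arrays titled 42.5 ppm. These values argue against a lower signal of the whole second array titled 85 ppm. All 10 members were lowest on that array, Dct at -3.63 and Tyrp1 at -5.38, which is consistent with fewer pigment cells or less pigment gene RNA in that culture, a hypothesis from the same data. The labels name a sort for the BrdU label and adhesion to collagen and fibronectin, neither of which is stated to remove melanocytes.

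The cytokine list was far from the others on the same array, with a median level of -1.21 against 0.96 to 1.01 on the other 3 arsenic arrays. It was the sole list of 33 so marked. Chance marks about 1 group in 20, so 1 mark among 33 lists is no more than chance would give.

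Among probes without a gene name, which enter no gene test of the report, 669 of 2111 tested passed between arsenic and control, 363 of them higher after arsenic and 306 lower.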

How the results depend on the processing

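The alternatives that left out edge columns, kept outlier spots, counted only genes with all probes passing or averaged probes for the lists were chosen only after the results were seen. Between the doses, 0 genes passed in limma under every alternative, with smallest adjusted p from 0.190 without 42.5 ppm replicate 2 to 0.528 without 85 ppm replicate 2. The labels share a set number between doses, and nothing states what the arrays of a set have in common. Same-numbered arrays did not deviate together over all genes (r = 0.059). This cannot exclude a factor shared by a set that affects some of the genes. With a replicate block 0 genes passed in limma (1625 at an unadjusted p under 0.05).

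Against the control, spike-in centring gave 5876 genes for arsenic (5447 higher and 429 lower), 4956 for 85 ppm and 5253 for 42.5 ppm. No filter gave 8037, 7291 and 7256, and every probe on its own 5596, 4014 and 4617, counted as probes. The mean of probes gave 1357 for 85 ppm and 1638 for 42.5 ppm, and 183 genes had all probes passing. Quantile normalisation gave 2256 higher genes and median centring 990 lower. Leaving out 1 arsenic array gave 0 to 1422 genes for arsenic, 0 without either 85 ppm array, 1422 without 42.5 ppm replicate 1 and 828 without replicate 2, 0 to 664 for 85 ppm and 0 to 0 for 42.5 ppm, with fewer arrays to estimate the spread. The control, at 1 array, cannot be left out. Apart from that loss and the counts as probes, the cause was not tested.

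The camera version with an estimated correlation has little power here. Of the lists, 7 passed between the doses and 1 against the control. With an estimated correlation 0 and 0 did, by random lists 14 and 9, without 1 array 3 to 9 and 1 to 4, and after quantile normalisation 2 against the control. The cell cycle list ran from -1.92 to 1.46 relative to all genes without 1 array, reversed at 1.46 without 42.5 ppm replicate 2. Without 42.5 ppm replicate 2 the cytokine (adjusted p = 0.0679), p53 (0.0679) and ribosome (0.112) lists were lost, without 42.5 ppm replicate 1 the melanocyte (0.486), leukocyte (0.196) and p53 (0.0710) lists, without 85 ppm replicate 1 the p53 (0.403) and ribosome (0.0930) lists, and without 85 ppm replicate 2 the cytokine (0.256), melanocyte (0.256), leukocyte (0.0611) and cell cycle (0.120) lists. The p53 list was also lost with the mean of probes (0.0943). The muscle list passed under each array left out.

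Single genes reversed, with at least 1 of the 2 values passing, for Itgb1 (3.38 with edge columns left out) and Mt4 (-0.15 with normexp). Rpl10 did so too (0.019 with spike-in centring, 0.13 with the mean of probes). Of 1191 alternative values for 92 genes named between the doses, 1174 kept direction and side of the threshold. The other 17 changed direction with neither value passing. Of 1366 for 106 genes named against the control, 1036 kept both, 300 no longer passed and 19 newly passed. Direction changed for 4 with at least 1 of the 2 values passing, the reversals above, and for 7 with neither passing. Of 56 for the 7 dose lists 34 kept both and 21 no longer passed. Of 24 for the suprabasal, melanocyte and ribosome lists against the control, 15 kept both, 2 no longer passed and 5 newly passed. The other 2 changed direction with neither value passing. With 45.2% of probes well above background on the control, 13 suprabasal genes have only a bound there.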

Other observations

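Mtap, Xist and the splits of the arrays were chosen only after the results were seen. So was the choice of which genes to set side by side in this part. Cdkn2a and Cdkn2b were named by the rule fixed beforehand.

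The inhibitor locus Cdkn2a and Cdkn2b differed between arrays titled 85 and 42.5 ppm. Cdkn2b lay at 4.07 and 5.08 on the arrays titled 85 ppm, at 0.11 and 2.31 on those titled 42.5 ppm and at 5.02 on the control. Mtap, the neighbouring gene for a methionine salvage enzyme, lay between 0.10 and 0.74 on all arsenic arrays and at 1.22 on the control. Xist, the RNA of the inactive X chromosome, and the Y-linked genes Ddx3y and Eif2s3y were well above background on every array, with Xist between 1.82 and 3.84, Eif2s3y between -0.74 and 2.34 and Ddx3y between -2.44 and 0.50. The second array titled 85 ppm was the lowest for both Y-linked genes and the highest for Xist.

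The 4 arsenic arrays can be split into pairs in 3 ways, too few for a share under 0.05. The titled doses gave 1498 genes at an unadjusted p under 0.05 and the highest other split 644, with 0 past the adjusted threshold in each by limma. The other splits put both doses in each group, so any difference between the doses adds to their spread. Setting 1 array against the other 4 can be done in 5 ways, also too few for a share under 0.05 together. The control alone gave 3471 genes past the threshold and each arsenic array alone 0 (187 to 444 at an unadjusted p under 0.05).

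The 6 spike-in RNAs differed between control and arsenic arrays by 0.60 to 2.28 on the log2 scale after scaling to the 75th percentile, with a median of 1.21, while the largest SD of any of them among arsenic arrays was 0.211. The SD between spots of one probe was 0.232 on the control and 0.0568 to 0.0603 on the arsenic arrays.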
